A study of Vitis vinifera with 12 samples.

How the data were processed

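Messenger RNA was measured by sequencing in berries of the grape cultivar Flame Seedless, a seedless table grape with red skin, at 4 ages after full bloom. The groups are the ages printed in the sample labels (40, 50, 60 and 80 days), with 3 libraries each, lettered a, b and c. Each column of the table was matched to its sample through the library code in the labels, and no column was left over. The series names a second cultivar for comparison, which was not analysed here.

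The authors deposited 1 table of FPKM values (fragments per kilobase of gene model, scaled to the total of mapped fragments), with 22580 identifiers in rows and 12 libraries in columns. Per the submitters' processing notes, the tools were Trimmomatic 0.36, FastQC, TopHat2, Cufflinks and edgeR, which are named there without their roles. The genome build, the annotation release and the filters behind the table are not given in the sources used here. Of the identifiers, 21791 have the VIT_ form and 789 are gene models labelled as new, and 1401 identifiers were listed at 0 in every library. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented and made into strand-specific libraries. The same protocol states that RNA from biological replicates was extracted separately and then pooled. It is therefore open whether libraries a, b and c of an age stem from separate plants, and the p-values measure only the spread between these libraries, which may be technical.

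The file does not pair its identifiers with gene names. None of them (0 of 22580) matched an identifier, synonym or accession among the 29591 genes of the RefSeq table for assembly ASM3070453v1, so no gene name, product or coordinate is given. The 24 gene lists (sugar, acid, colour, cell wall, hormone, photosynthesis, cell cycle, defence and other themes) and the 14 reference loci that had been fixed before the data were examined rested on product names, so none of them was tested. Gene models are described instead by their direction, timing, level and place in the identifier order. The identifiers are used exactly as the file gives them.

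Values were transformed to log2(FPKM + 1), that is with a pseudocount of 1, and 14579 gene models with an FPKM of at least 1 in at least 3 of the 12 libraries were tested. A linear model with a mean per age was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3), with a trended prior variance and no further scaling between libraries. A gene model was called changed at a Benjamini-Hochberg adjusted p under 0.05 together with a difference of at least 1 on this log2 scale. Differences on this scale understate the change of low gene models. Change at any age was tested with limma's moderated F test and a range of the age means of at least 1. A gene model was said to peak at an intermediate age when it was called higher at 50 or at 60 days than at both 40 and 80 days. Because both contrasts share the middle age, the chance count was simulated. It was drawn 20 times with no change and 20 times with intermediate levels on the straight line between the 40 and 80 day means. Noise was drawn independently per value with limma's moderated spread of each gene model. Deviations that the gene models of a library share were therefore absent. Measures per library were compared between ages with an exact permutation test over all 15400 partitions of the 12 libraries into 4 groups of 3.

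The depth of the libraries is unknown, since the table gives no counts. In 66 pairs of libraries, the ratios of values under 0.5 FPKM were examined for steps of 1 read. The fullest bin of 0.005 (log2) held between 0.46% and 2.43% of the gene models, so relative depth was not recovered and no count test was run. The median standard error of a log2 difference between 2 ages was 0.14. Simulated data took the real mean levels and limma's moderated spreads of the 14579 gene models, with independent noise, so false calls may be understated. With 200 of them changed between 80 and 40 days, the fit recovered 58 of 67 changes of 1.5 and 66 of 67 changes of 2 (log2). It recovered 65 of 66 changes of 3, with 2 false calls in all. In simulations of the other comparisons, 62 of 67 changes of 1.5 were recovered from 40 to 50 days with 8 false calls, 64 of 67 from 50 to 60 days with 0, and 64 of 67 from 60 to 80 days with 3.

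The identifiers printed were chosen by a rule set before the data were examined: the largest rises and falls among called gene models with a mean FPKM of at least 10 at the higher age and no overlap between the 3 libraries of either age. The rule also asked for a product name, which no identifier has, so that part was dropped. It set 3 rises and 3 falls per comparison and 3 peaks, and 2 of each are given here. The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, no minimum difference, the replicate letter as a block, a fit to only the ages compared, limma without the trend, and leaving out each library in turn. Removal of the 10 most abundant gene models was added after seeing the data. The rest of each library was then rescaled to the same total, wherever results without these gene models are given. The values left change only through this rescaling. It also evens out the summed FPKM, which was 1002500 ± 47411 (SD, n = 3) at 60 days and 1155400 ± 49538 at 80 days. Shifts under this setting therefore cannot be credited to the abundant gene models alone. The groupings by expression level and by identifier order were also added after seeing the data. Neighbours are tested VIT_ identifiers that follow each other in the order of their numbers within a block, the part of the identifier before the letter g. Calculations outside R used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.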

Results

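Transcript levels were measured in 12 libraries from Flame Seedless berries, 3 at each of 40, 50, 60 and 80 days after full bloom, to follow gene expression through berry development. Between 13166 and 14326 gene models reached 1 FPKM per library. Their number was 13975 ± 304 (SD, n = 3) at 40 days and 13354 ± 202 at 80 days. The difference between ages gave p = 0.0468 in an exact permutation test, and 0.14 after adjustment over the 4 library measures compared. The 10 most abundant gene models of a library held 21.8% ± 1.62 of its summed FPKM at 40 days, 27.2% ± 2.81 at 50 days, 24.8% ± 1.002 at 60 days and 28.1% ± 3.75 at 80 days (exact permutation p = 0.0702, adjusted 0.14). Gene models labelled as new held 1.28% ± 0.264 at 40 days and 1.08% ± 0.0534 at 80 days (exact permutation p = 0.695), and the number of values at 0 did not separate the ages either (exact permutation p = 0.331).

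Libraries grouped by age. Pearson correlations of log2(FPKM + 1) across gene models, which are not independent replicates, were 0.977 to 0.984 within an age. They were 0.927 to 0.957 between 40 and 50 days, 0.946 to 0.972 between 50 and 60 days, 0.953 to 0.973 between 60 and 80 days and 0.846 to 0.892 between 40 and 80 days. The first principal component held 60.0% of the variance and ordered the ages from 40 to 80 days without overlap. Along it, 60-day replicate c scored 10.6, against 28.8 and 35.1 for the other 60-day libraries and -16.1 to -4.95 for the 50-day libraries. The second component, with 10.5% of the variance, set 50 and 60 days apart from the first and last ages.

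**Figure D1:**
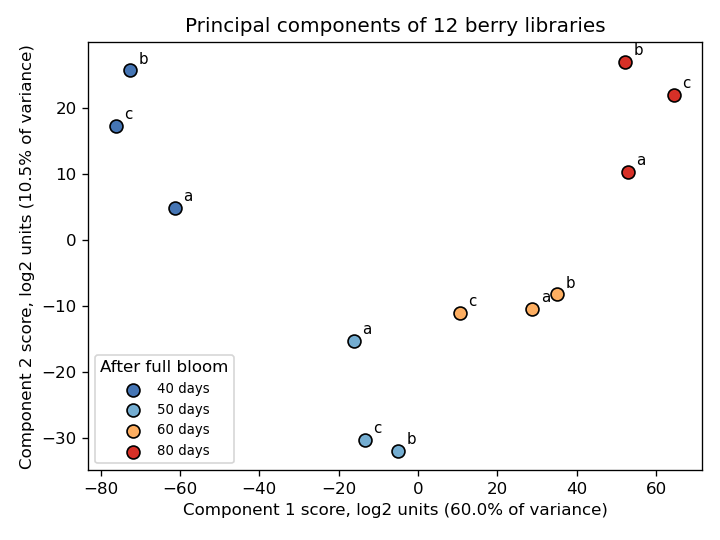
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2(FPKM + 1), in log2 units; each point is a library, coloured by age and lettered by replicate. The ages follow each other along the first component, and 60-day replicate c, at 10.6, is the 60-day library nearest to the 50-day ones.

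Over the whole period, from 40 to 80 days, 1013 gene models rose and 2046 fell, 20.98% of the 14579 tested (limma, adjusted p under 0.05 and a log2 difference of at least 1). Large falls were more numerous than large rises: 676 gene models fell and 220 rose by at least 2 on the log2 scale, and 109 fell and 33 rose by at least 4. Among gene models that met the rule for naming, the largest rise was that of VIT_12s0057g01110, from 1.16 ± 0.677 FPKM (SD, n = 3) to 434 ± 163 FPKM, a log2 difference of 7.62 ± 0.456 (SE; limma adjusted p = 6.11e-07). VIT_10s0003g05420 rose from 1.14 ± 1.29 to 215 ± 50.6 FPKM (6.80 ± 0.396, adjusted p = 5.59e-07). VIT_11s0016g05840 fell from 411 ± 73.8 to 0.782 ± 0.240 FPKM (-7.85 ± 0.493, adjusted p = 8.17e-07), and VIT_12s0059g01240 fell from 531 ± 219 to 4.10 ± 5.53 FPKM (-7.16 ± 0.719, adjusted p = 1.19e-05).

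Falls outnumbered rises among weakly and moderately expressed gene models. The level used is the mean over all 12 libraries, which the change itself helps to set. Part of the contrast between classes may therefore follow from the grouping. Of those with a mean under 3 FPKM over the 12 libraries, 153 rose and 531 fell, and of those from 3 to 10 FPKM, 208 rose and 613 fell. From 30 to 100 FPKM the numbers were 226 and 262. From 100 to 300 FPKM, 119 rose and 112 fell, and at 300 FPKM or more 72 rose and 55 fell. Of the 92 gene models with a mean of at least 1000 FPKM, 23 rose and 18 fell. Among the 332 tested gene models labelled as new, 27 rose and 38 fell, 65 in all, where sets of VIT_ gene models matched on level held 62 to 91 called members (95% of 10000 draws). Gene models that went from under 1 FPKM in every 40-day library to at least 10 FPKM in every 80-day library numbered 12, and 35 went the other way. Without 80-day replicate b the latter count was 61, but leaving out a library also loosens this rule, so the count can only stay or rise.

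**Figure D2:**
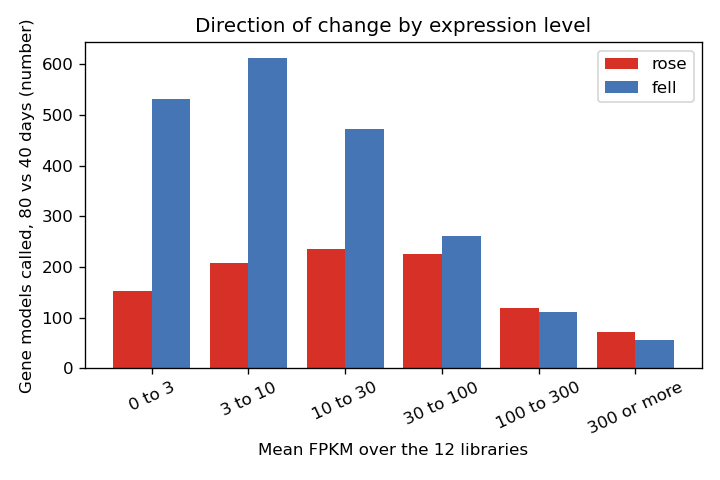
Number of gene models called (y axis) between 80 and 40 days by mean FPKM over the 12 libraries (x axis), with red bars for those that rose and blue bars for those that fell. Falls outnumber rises 531 to 153 in the lowest class, and rises outnumber falls 72 to 55 in the highest.

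In 3003 of the 3059 gene models called between 40 and 80 days, the 3 libraries of each age did not overlap. Over all tested gene models 65.5% did not overlap, where chance gives 10%. When the minimum difference was dropped, 8859 gene models passed and 49.4% of them rose, against 33.1% with it. Quantile normalization, which moved the median log2 difference of all gene models from 0.00 to 0.11, gave 42.6%.

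The first interval, from 40 to 50 days, held the most calls of the 3 intervals, with 305 gene models rising and 865 falling. With no minimum difference 2021 rose and 2651 fell, so that 43.3% of the calls rose instead of 26.1%. VIT_12s0057g01110 rose here already, to 133 ± 84.1 FPKM (log2 difference 5.81 ± 0.456, limma adjusted p = 3.12e-05). VIT_01s0127g00050 rose from 3.10 ± 2.32 to 58.3 ± 13.5 FPKM (4.02 ± 0.396, adjusted p = 9.74e-05), stood at 15.2 ± 3.43 FPKM at 60 days and at 72.8 ± 20.4 FPKM at 80 days. VIT_13s0019g00330 fell from 1718 ± 614 to 96.5 ± 33.2 FPKM (-4.14 ± 0.459, adjusted p = 0.000164) and was at 14.7 ± 4.96 FPKM by 80 days. VIT_01s0011g02710 fell from a very uneven 289 ± 303 FPKM to 7.14 ± 7.36 FPKM (-5.002 ± 1.02, adjusted p = 0.00413).

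Of the gene models with a mean of at least 1000 FPKM, 12 rose and 3 fell in this interval. Of those with a mean under 10 FPKM, 99 rose and 511 fell. These means also take in the later ages, so the classes are not independent of the change. The mean squared log2 difference between the ages, less the part that the spread between libraries gives, was 0.325 per gene model, and 0.284 to 0.370 when each library was left out in turn. It was 0.184 (0.153 to 0.222) from 50 to 60 days and 0.176 (0.142 to 0.200) from 60 to 80 days, a longer interval. With a pseudocount of 0.1 the values were 0.493, 0.291 and 0.306. With the 10 most abundant gene models removed and the rest rescaled, the later intervals gave 0.193 and 0.205, so their order depended on the settings.

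**Figure D3:**
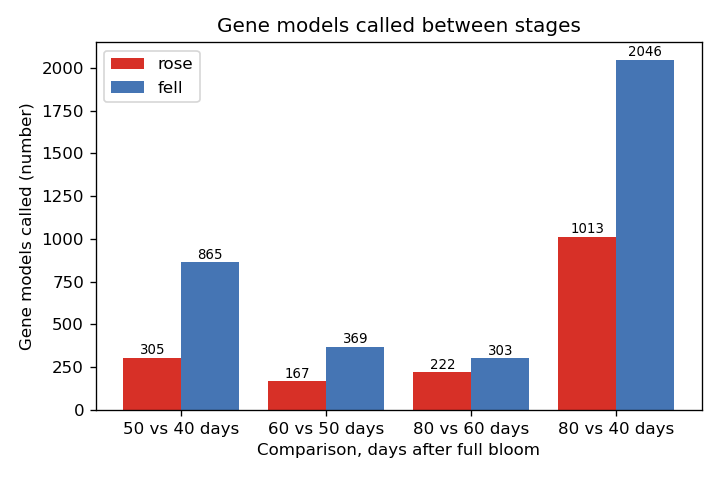
Number of gene models called (y axis) in each comparison of ages (x axis), with red bars for those that rose and blue bars for those that fell. The 40 to 50 day interval has 305 rises and 865 falls, and the comparison of 80 with 40 days 1013 and 2046.

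Between 50 and 60 days, 167 gene models rose and 369 fell. With no minimum difference the numbers were 1113 and 1165, and the share that rose went from 31.2% to 48.9%. A run of 10 neighbouring identifiers in the VIT_12s0057 block rose together. Their median level per library was 3.14 to 4.08 FPKM at 50 days and 66.1 to 89.7 FPKM at 60 days, and their median log2 difference was 4.204, each member being called. Its member VIT_12s0057g00100 rose from 2.61 ± 1.60 to 101 ± 6.05 FPKM (4.91 ± 0.383, limma adjusted p = 0.000192). VIT_14s0006g02950 rose from 0.157 ± 0.153 to 66.1 ± 6.92 FPKM (5.86 ± 0.452, adjusted p = 0.000192). At 80 days the run stayed high, with medians of 160 and 181 FPKM in replicates a and c, and 60.6 FPKM in replicate b.

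**Figure D4:**
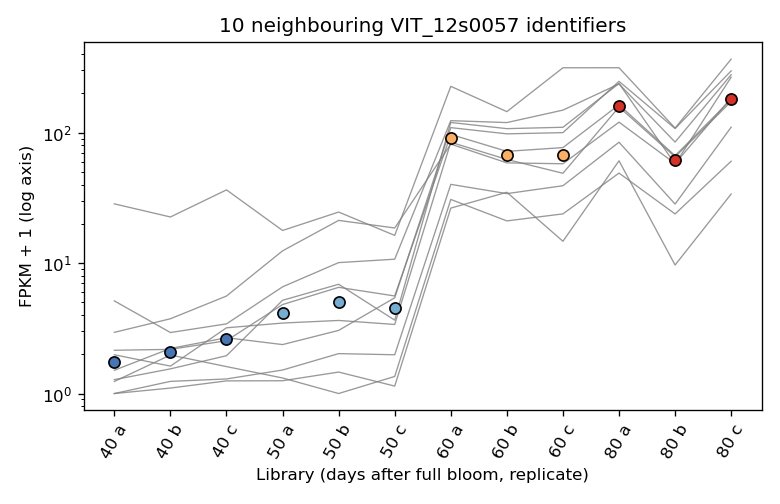
FPKM + 1 on a log axis (y axis) in each of the 12 libraries (x axis, by age and replicate) of the 10 neighbouring VIT_12s0057 identifiers; grey lines join the values of an identifier and points mark the library medians. The medians lie at 3.14 to 4.08 FPKM at 50 days and 66.1 to 89.7 FPKM at 60 days.

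Among the falls of this interval were 5 neighbouring identifiers of the VIT_08s0007 block, with a median log2 difference of -2.91. One of them, VIT_08s0007g08020, stood at 94.2 ± 9.70 FPKM at 40 days, 586 ± 124 FPKM at 50 days and 42.7 ± 31.7 FPKM at 60 days (60 against 50 days -4.15 ± 0.862, adjusted p = 0.0115). VIT_17s0000g09810 fell from 121 ± 46.7 to 6.51 ± 3.27 FPKM (-4.02 ± 0.524, adjusted p = 0.00175). Gene models with a mean of 100 to 1000 FPKM fell more often than they rose, 72 against 18. The number called in this interval rested on single libraries. It was 326 without 60-day replicate b and 332 without 50-day replicate c, against 536 with all.

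From 60 to 80 days, 222 gene models rose and 303 fell, and 39 of the rises and 40 of the falls were of at least 2 on the log2 scale. VIT_08s0007g02360 rose from 2.73 ± 1.17 to 69.6 ± 46.3 FPKM (3.97 ± 0.690, limma adjusted p = 0.00445). VIT_14s0066g00700, which had been at 99.8 ± 55.0 FPKM at 50 days, rose from 6.35 ± 4.197 to 76.3 ± 29.98 FPKM (3.47 ± 0.540, adjusted p = 0.00308). VIT_19s0085g00790 fell from 60.6 ± 19.7 to 3.91 ± 0.872 FPKM (-3.62 ± 0.290, adjusted p = 0.000245), after 5.49 ± 2.02 FPKM at 50 days. VIT_06s0004g04640 fell from 109 ± 48.3 to 7.90 ± 1.67 FPKM (-3.53 ± 0.643, adjusted p = 0.00547). Without 60-day replicate c, 334 gene models were called instead of 525. The share that rose, 42.3% of the calls, was 27.0% when the 10 most abundant gene models were removed and the rest rescaled, a step that moved the median log2 difference of all gene models from 0.01 to -0.14, and 29.5% with a pseudocount of 0.1. With no minimum difference the direction turned, with 1617 gene models rising and 1366 falling (54.2% rising).

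Taking the 4 ages together, 3540 gene models changed (limma F test, adjusted p under 0.05 and a range of at least 1), 24.3% of those tested. By interval, 12747 of the tested gene models were called in none. Of the courses with a call, the most frequent was a fall between 40 and 50 days with no call in either later interval, in 642 gene models, and 235 rose in the same way. A fall called only between 50 and 60 days was seen in 202 gene models (122 without 50-day replicate c, 112 without 60-day replicate b), and a rise in 95 (55 without 50-day replicate c). In the last interval alone 157 fell (100 without 60-day replicate c) and 139 rose (84 without it). A pseudocount of 0.1 raised the rises of the first interval alone to 354 and the falls of the last alone to 287, and a mean of at least 5 FPKM lowered the falls of the first alone to 319 and the rises of the last alone to 84. With the 10 most abundant gene models removed and the rest rescaled, 272 fell in the last interval alone. With no minimum difference, falls and rises in a single interval numbered 1580 and 1190 in the first, 502 and 550 in the second and 547 and 811 in the last, so that rises outnumbered falls in both later intervals. Gene models that fell over the whole period had reached a median 51.3% of their log2 change by 50 days and 73.0% by 60 days. Those that rose had reached 42.2% and 64.2%. This order depended on the setting: with a pseudocount of 0.1 the values were 46.6% and 67.5% for falls and 46.4% and 69.2% for rises, and without the 10 most abundant gene models 48.4% and 65.3% for falls and 45.7% and 73.6% for rises.

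A peak at an intermediate age was called in 53 gene models, 31 at 50 days, 27 at 60 days and 5 of these at both. Of the 53, 46 were not called between 40 and 80 days, a comparison in which only 20.98% of all tested gene models were called. In 20 simulations the highest chance count was 0 with no change and 4 with levels on a straight line between the first and last ages. The former was near fixed in advance, since almost nothing passes the adjusted p when no gene model changes. Neither simulation held courses that change early and then level off, so chance peaks among those were not counted. VIT_19s0014g00440 was at 0.154 ± 0.170 FPKM at 40 days, 1.27 ± 1.18 FPKM at 50 days, 28.3 ± 8.78 FPKM at 60 days and 2.18 ± 1.27 FPKM at 80 days. VIT_08s0007g08020, described above, peaked at 50 days. A low point at an intermediate age, by the mirrored rule, was called in 72 gene models.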

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

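The 16 changes printed by identifier were the 2 largest rises and 2 largest falls under the naming rule in each comparison. These changes kept their direction and stayed past the threshold in all 352 values from the alternatives and from leaving out each library. They had been picked for their size, with log2 differences of at least 3.47 in either direction. Their stability was therefore near fixed by the choice and says little about other calls. Without a minimum difference, 4672 gene models passed from 40 to 50 days, 2278 from 50 to 60, 2983 from 60 to 80 and 8859 from 40 to 80, with 9532 at any age and 330 intermediate peaks; the rule itself is looser, so it adds calls. A pseudocount of 0.1 gave 847 calls from 60 to 80 days, where the cause was not tested. Leaving out each library in turn gave 326 (without 60-day replicate b) to 647 (without 50-day replicate b) calls from 50 to 60 days, and 334 (without 60-day replicate c) to 577 (without 80-day replicate a) from 60 to 80 days. Over the left-out libraries, the lowest share of calls kept was 75.1% from 40 to 50 days, 57.3% from 50 to 60, 60.6% from 60 to 80 and 88.6% from 40 to 80, and no call turned direction. With a mean of at least 5 FPKM, which tests fewer gene models, the shares were 66.8%, 83.6%, 73.5% and 67.1%. The other total counts of gene models changed, at any age and peaks included, stayed within 1.5 times their value, but falls alone did not: they went to 524 (40 to 50 days) and 1267 (40 to 80 days) with a mean of at least 5 FPKM. From 60 to 80 days they went to 597 with a pseudocount of 0.1 and to 179 without 60-day replicate c. They went to 490 when the 10 most abundant gene models were removed and the rest rescaled. From 50 to 60 days they went to 231 without 50-day replicate c and 203 without 60-day replicate b, and rises to 101 without 50-day replicate c. With the replicate letter as a block, the counts were 1147, 512, 521 and 3057 for the intervals in order and the whole period. The letters showed no clear pairing of the libraries. Deviations of libraries with the same letter correlated from -0.298 to 0.249 (median 0.018), over 0.1 in 4 of 18 pairs. With different letters they correlated from -0.247 to 0.408 (median -0.029), over 0.1 in 7 of 36 pairs. The highest correlation of all, 0.408, joined 40-day replicate b with 50-day replicate a. The planned tests of the gene lists were not run, since no identifier carried a product name. Depth is unknown, so counting error in weakly expressed gene models cannot be separated from other spread.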

Other observations

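The tests of neighbouring identifiers, of the VIT_12s0057 run, of the excess of falls and of 60-day replicate c were chosen after seeing the results. The splits of the libraries were planned, but not the breakdown of those that reached the count of peaks. Neighbouring gene models were called alike more often than in most shuffles. Of 13621 adjacent pairs of tested identifiers within a block, 468 were called in the same direction from 40 to 80 days, where 1000 shuffles of the calls gave a median of 333.5 and at most 383 (permutation p = 0.001, the smallest these shuffles can give; adjusted 0.0013 over 4 comparisons). The counts were 90 against at most 78 from 40 to 50 days and 36 against at most 22 from 50 to 60 days. The former was 64 without 40-day replicate b and without 40-day replicate c, and the latter 22, 20 and 18 without 50-day replicate a, 50-day replicate c and 60-day replicate b. The 36 pairs from 50 to 60 days include those within the run of 10 VIT_12s0057 identifiers and the run of 5 VIT_08s0007 identifiers. Shuffles were not compared with a count that leaves these runs out. From 60 to 80 days 19 pairs compared with a median of 9 and at most 21 in the shuffles (permutation p = 0.003), and 6 pairs were left without 60-day replicate c, where a pseudocount of 0.1 gave 46 and removal of the 10 most abundant gene models 38. With a mean of at least 5 FPKM the counts were 50 from 40 to 50 days and 281 from 40 to 80 days, and dropping the minimum difference raised them to 856, 217, 371 and 2801 for the intervals in order and the whole period. Shuffles were run only for the settings of the report, so whether these other counts exceed chance is open. Besides the VIT_12s0057 run, 6 neighbouring identifiers of the VIT_12s0028 block fell from 40 to 80 days with a median log2 difference of -1.43, and 5 of the VIT_14s0128 block fell with a median of -1.35. Shuffles gave up to 4 runs of 5 or more in that comparison, so these shorter runs do not stand out.

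The run of 10 VIT_12s0057 identifiers that rose between 50 and 60 days is longer than the longest run in 300 shuffles of the calls, which was 4. Reads of a single gene spread over near-identical copies would give every member the same fold; a first comparison, of the largest member's lowest fold between any 60-day and 50-day library with the smallest member's highest, gave a quotient of 8.06 but decides nothing, since its largest member is listed near 0 at 50 days. Over the 7 members with a mean of at least 1 FPKM at 50 days, a limit chosen after the first quotient was seen, the quotient was 3.10, which argues against a single source for all of them. This rests on VIT_12s0057g00180, picked out after its values were seen, with a fold of 3.96; without it the quotient was 1.07, which left the others open, and the quotient for 80 over 40 days, examined after that, was 3.75 over the 5 others with a mean of at least 1 FPKM at 40 days. That value rests on VIT_12s0057g00190, with a fold of 9.31. Over the 4 members left without it the quotient was 0.443, so a single source stays open for the members other than these. The quotients address only a single source of all reads. Reads shared in part stay open for every member, VIT_12s0057g00180 and VIT_12s0057g00190 included.

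More gene models fell than rose from 40 to 80 days, 2046 against 1013, but with no minimum difference 4481 fell and 4378 rose (49.4% rising), so the excess is one of larger changes. The first test of whether scaling or a few abundant gene models account for this left the question open: over 3 other scalings the share of calls rising reached at most 42.6% (quantile normalization; 33.3% with median-ratio scaling and 30.8% without the 10 most abundant), short of the 45% set as needed and above the 40% set as excluding it. The median log2 difference of all tested gene models was examined only after that result and was 0.0024. It shows no net lowering of the listed values. A lowering by abundant gene models that was offset by rises would leave the same median, so it does not decide the question. Scaling may still account for part of the excess. If deeper 40-day libraries had detected more weak gene models, the excess should shrink against 40-day replicate c, which has 4624 values at 0 where the 80-day libraries have 4286 to 4731; with that library alone at 40 days, assumed to vary like the others, 35.6% of the calls rose. That 40-day replicate was matched on values at 0 only. It still had 13808 gene models at 1 FPKM or more, against 13166 to 13567 in the 80-day libraries, so depth stays open. The age of the berries stays open too, as an untested explanation.

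The 60-day replicate c lay on the earlier side of replicates a and b. Its deviation from them had a slope of -0.162 ± 0.0041 on the difference between 80 and 40 days, which uses no 60-day library. The SE is over blocks of gene models and does not measure the spread between libraries. Across gene models, which are not independent, r was -0.497. Replicates a and b, each against the other 60-day libraries, had slopes of 0.052 and 0.11, so b lay on the later side. On the same axis the 50-day libraries ran from -0.044 to 0.057. In the 9 libraries of other ages the slopes ran from -0.095 to 0.109, but the 40-day and 80-day libraries had other axes, so their slopes are not on the same scale. The slope of replicate c was -0.16 after quantile normalization and -0.162 after median-ratio scaling. A single scaling factor shifts nearly all log2 values of a library alike and hardly moves such a slope. These values were therefore near fixed in advance and say little about scaling. Replicate c kept a slope of -0.167 over the 4407 gene models with a mean of at least 30 FPKM, against noise of weak ones. Its mean correlation with the other 60-day libraries exceeded its highest with another age by 0.0107 (0.983 against 0.972), against an exchange with a 50-day library. Berries that were slightly less advanced are a candidate explanation, which was not tested, since no measure of ripeness was analysed here.

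Other splits of the libraries were also fitted. For change at any age, the real grouping gave 3540 calls, the highest of 100 splits into 4 groups of 3, with 1763 next. Its share, 1 of 100, is the smallest these splits can give and argues against a chance arrangement of these libraries. If the libraries of an age stem from a single pool, the splits cannot address chance differences between pools. For intermediate peaks, 6 of 100 splits reached the real count of 53 and the highest gave 814; by this count chance is not excluded. The 5 other splits that reached it each put all 3 libraries of 40 or of 80 days into a middle group, and the rest gave at most 2. Such a split can count the real difference between ages as peaks, so the planned count does not measure chance alone and cannot decide the question. The breakdown was not part of the planned test and does not alter its outcome. Simulations with no change gave at most 0 peaks and those on a straight line at most 4. With the limits given above, they do not settle the question. For each pair of ages the 10 splits are too few for a share under 0.05; the real split gave 1170, 536, 525 and 3059 calls for the intervals in order and the whole period (1 split as large in each), and the highest other split gave 1, 1, 3 and 0.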
